A study of Homo sapiens with 6 samples.

How the data were processed

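Total RNA from spheroid cultures of SW480 and SW620 was labelled with biotin as fragmented sense-strand cDNA, per the labels' protocols, and hybridised to 6 Affymetrix whole-transcript arrays, 3 per line. The series' design text calls the 3 arrays of a line technical replicates. The deposited table holds log2 expression values, 1 per feature and array, made with Partek and RMA per the submitters' processing notes, and their versions and settings are not given in the sources used here. RMA subtracts background, equalises the distribution between arrays and summarises probes on a log scale. The base of the logarithm is not stated and was taken as 2 from the range of the values, 1.99 to 13.9, so every fold given rests on that reading. Neither detection calls nor unprocessed intensities were used here, so the background step could not be varied, and RMA's background can understate the fold of dim genes.

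The table has 53616 features. A table of platform annotation gave exactly 1 gene symbol to 16098 of them, several to 0 and none here to 37518, and all 16098 matched a human gene table (assembly GRCh38.p14), which was used only for names, chromosomes and the order of genes. Y-linked genes and XIST, 11 in all, were left out. For the 778 genes with more than 1 feature, the feature with the highest mean over the 6 arrays stood for the gene, which left 14873 genes, 11910 of them protein-coding. No filter on dim features was applied.

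The lines were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, SW620 minus SW480, no covariates, 8.40 prior degrees of freedom), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Standard errors are the moderated ones of this fit and n is 3 arrays per line. Counts are also given at a minimum difference of 2-fold. Gene lists and chromosomes were tested with camera at a preset correlation of 0.01 between genes, adjusted over all lists or over all 23 chromosomes, with an estimated correlation, fry and ranks beside it. Changed members of a list were counted at the adjustment over all genes and again adjusted over the list alone.

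The samples' grouping, tests, lists, alternatives and the rule for named genes were set before the data were examined. The rule takes the 10 highest and 10 lowest differences among genes past the threshold whose arrays do not overlap between lines, without Y-linked genes and most non-coding or olfactory symbols. From each list it takes up to 4 changed members with the largest difference, or the member with the smallest p where none changed, and for up to 3 shifted chromosomes the 3 largest differences in the direction of the shift. The rule also named a pair of genes that are not reported here. Of 27 lists, 25 had at least 1 measured member and the remaining ones, integrins and ABC transporters, were not analysed here. Lists were measured in part, from 7 of 30 antigen presentation genes and 8 of 41 cancer-testis antigen genes to 25 of 26 Notch genes, so a count describes the measured members and not the whole pathway.

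The alternatives were a repeat quantile normalization, centring on the median or on the 75th percentile, cyclic loess, filters at the median and at the 25th percentile feature, a trended and robust variance model, the mean of all features of a gene, all features tested separately, the replicate number as a block, treat with a minimum of 1.2-fold, other thresholds, and leaving out each array in turn. Symbol families, stretches of neighbouring genes and a count over protein-coding genes were added after the data had been seen.

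The gene fit was tested on simulated data for this comparison with 14873 genes. Of 50 genes changed by 0.5 on the log2 scale, 45 were recovered, and of 50 each changed by 1, 2 or 3, all 50 were. Among 208 calls 13 were false (6.25%), and 0 genes were called when nothing was changed. For sets, 20 of 20 shifted by 0.3 were recovered and 0 of 80 unshifted sets were called. The simulated genes varied independently and no gene outside the shifted sets was changed, whereas many other genes differed between the lines. The set numbers therefore do not measure how well camera would find a shifted list in the real data. The gene numbers are limited too. Far fewer genes were changed than the 5294 called in the real data, and the spread was that between technical replicates. The share of false calls need not hold for the real comparison.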

Results

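Messenger RNA was profiled on 6 whole-transcript arrays in spheroid cultures of a pair of human colorectal cancer lines that came from the same patient. SW480 was grown from the primary tumour and SW620 from a lymph node metastasis. Each line was kept as floating spheres in serum-free medium with growth factors, a culture used to enrich cells able to start tumours, and 3 arrays were run per line. The stated purpose was to find how this tumour-initiating compartment differs between the lines. The deposited values are on a log2 scale and ran from 1.99 to 13.9, and the median of each array lay between 4.04 and 4.07. Arrays of the same line correlated across features with r from 0.988 to 0.992, and arrays of different lines with r from 0.963 to 0.965; features are not independent replicates. The first principal component separated the lines and held 68.5% of the variance. The median standard deviation of a gene between arrays of a line was 0.0956 in SW480 and 0.105 in SW620 on the log2 scale. No 2 arrays held the same values. The submitters describe the 3 arrays of a line as technical replicates. The p-values of limma and fry therefore measure only the spread between such arrays, not between separate cultures. Camera sets the genes of a list or chromosome against other genes, so its p-values do not measure a spread between cultures either. The number of arrays limits the precision.

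The spheroids of the lines differed most in DKK4, a secreted Wnt antagonist that is itself switched on by Wnt signalling. Its level was 13.12 ± 0.0175 (mean ± SD, n = 3) in SW480 and 5.74 ± 0.17 (n = 3) in SW620, a 167-fold lower signal in SW620 (log2 difference -7.38, standard error 0.0956). Among the genes higher in SW620, HLTF, a chromatin remodeller and ubiquitin ligase of the DNA damage response, had the largest difference on the brighter of its features, 43.7-fold (5.45, standard error 0.0890), a rank it loses when its features are averaged (2.76). In limma's moderated test, 5294 of 14873 genes differed at an adjusted p below 0.05, with 2388 higher and 2906 lower in SW620. In this count the lean toward lower genes depends on the scaling, since centring on the 75th percentile gave 2685 higher and 2685 lower. At least a 2-fold difference was found for 904 of the 5294 genes, of which 345 were higher and 559 lower. At that size, centring on the 75th percentile gave 364 higher and 532 lower. Genes brighter than the median feature made up most of the 5294 calls, since 49.9% of 9474 such genes changed, against 10.5% of 5399 dimmer ones.

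**Figure D1:**
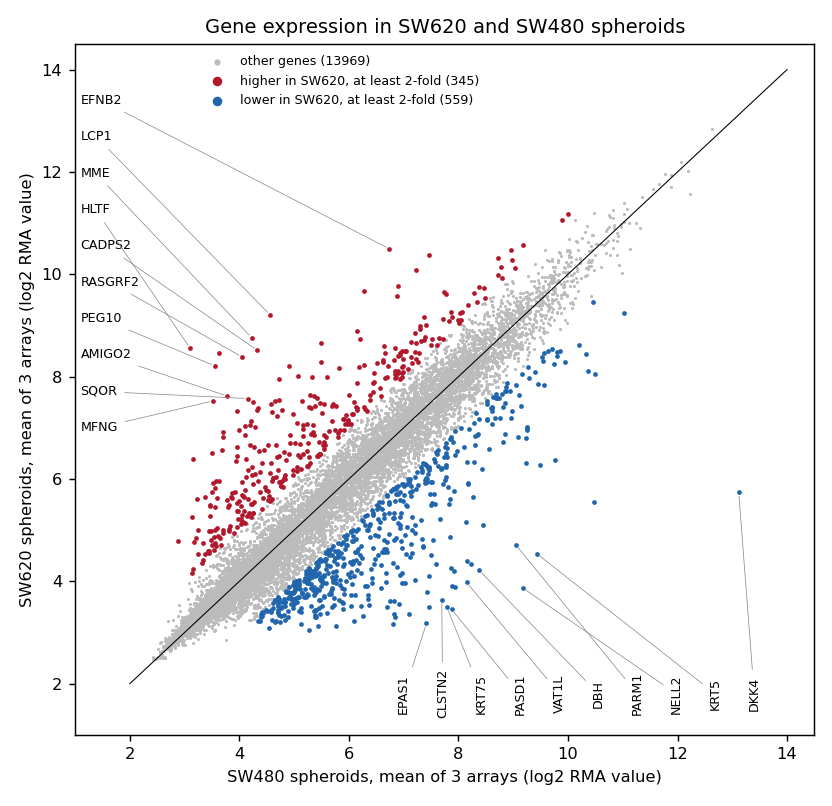
Mean log2 level of each gene in SW480 spheroids (x axis) against SW620 spheroids (y axis), 3 arrays per line, with genes at an adjusted p below 0.05 and at least 2-fold apart in red (higher in SW620) or blue (lower). The 345 genes higher and the 559 genes lower in SW620 lie on either side of the diagonal, with DKK4 farthest below it.

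Among the 10 genes with the largest rise in SW620, HLTF was followed by PEG10, an imprinted gene of retrotransposon origin (4.66, or 25.2-fold), and LCP1, the actin-bundling protein L-plastin (4.65, standard error 0.0810, or 25.1-fold). MME, the cell-surface peptidase neprilysin, rose 23.2-fold. RASGRF2, an exchange factor for Ras and Rac, rose 20.2-fold, and CADPS2, which primes secretory vesicles for release, rose 18.2-fold. MFNG, a glycosyltransferase that modifies Notch receptors, went from 3.52 to 7.53. The adhesion molecule AMIGO2 (14.3-fold), the ephrin ligand EFNB2 (13.5-fold) and the mitochondrial sulfide oxidase SQOR (10.7-fold) completed the group. At the other end, NELL2, a secreted protein first known from neurons, was 40.0-fold lower in SW620 (-5.32, standard error 0.0984). The keratins KRT5 and KRT75 were lower by factors of 29.6 and 19.7. PASD1 (21.5-fold), the mucin-like PARM1 (20.2-fold), VAT1L (18.0-fold) and the calsyntenin CLSTN2 (16.6-fold) were also lower. So were EPAS1, the hypoxia-inducible factor HIF-2 alpha (18.9-fold), and DBH, the enzyme that makes noradrenaline (18.0-fold). These 20 genes were taken from those whose arrays do not overlap between the lines. HLTF and MFNG in SW480, and PASD1, KRT75 and EPAS1 in SW620, had means below the 25th percentile feature (3.53). Their folds therefore rest on a level near the floor. PEG10, AMIGO2 and RASGRF2 in SW480, and CLSTN2, NELL2 and VAT1L in SW620, had means below the median feature (4.065). The folds of these genes are uncertain too.

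A further feature of HLTF was dim and differed by 0.0683 only (adjusted p = 0.612), so the mean of its features differed by 2.76, a 6.77-fold rise in place of 43.7-fold. The other feature of RASGRF2 differed by 1.49, and the mean of its features by 2.91, a 7.52-fold rise in place of 20.2-fold. At these means HLTF and RASGRF2 lie below SQOR (3.42) and would not be among the 10 largest rises. The other feature of NELL2 differed by -3.64, and the mean of its features was 22.3-fold lower in SW620.

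**Figure D2:**
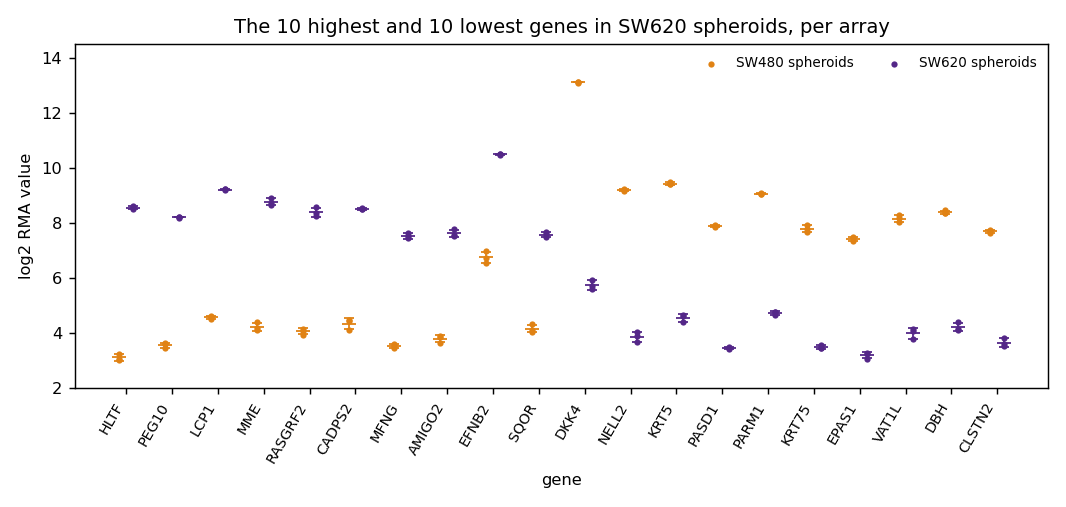
Log2 level on each of the 6 arrays (points) for the 10 genes with the largest rise and the 10 with the largest fall in SW620 relative to SW480 spheroids, with bars for the mean and SD of each line. Genes were chosen so that the lines do not overlap, and the SW480 arrays of DKK4 sit at a mean of 13.12 against 5.74 in SW620.

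The stem cell and surface marker lists bear on the tumour-initiating compartment, and their best-known members went in opposite directions. No sorted fraction or adherent culture was among the arrays. A difference therefore cannot be assigned to that compartment rather than to the cells of a line in general. LGR5, a receptor that marks intestinal stem cells, was 8.95-fold higher in SW620 (3.16, standard error 0.0855; 5.49 ± 0.0575 in SW480 and 8.65 ± 0.0920 in SW620, n = 3 each). The stem cell markers SMOC2 (6.56-fold), PROM1, which encodes CD133 (5.20-fold), and EPHB3 (2.98-fold) also rose. RNF43, AXIN2, CDCA7, LRIG1 and ASCL2, named here after their values were seen, fell, with RNF43 2.81-fold lower and AXIN2 1.59-fold lower. Of 16 measured intestinal stem cell markers, 5 rose, 5 fell and 6 did not pass the test, and the counts adjusted over the list alone were the same 5 and 5. Of 10 measured members of the tumour-initiating marker list, 5 rose and 4 fell, as they did when adjusted over the list alone. None of the aldehyde dehydrogenase genes on that list was measured, so the counts cover the other markers only. Here CD24, a surface glycoprotein, rose 7.59-fold, while the hyaluronan receptor CD44 was 6.17-fold lower (-2.62, standard error 0.0829) and the chemokine receptor CXCR4 was 12.2-fold lower (-3.61, standard error 0.0990). DCLK1, named here after its values were seen, was 4.92-fold lower, with a SW620 mean (3.13) below the 25th percentile feature (3.53). Among 17 measured pluripotency and embryonic factors 1 changed, both over all genes and adjusted over the list alone. It was SOX2, a transcription factor of embryonic stem cells, which rose 7.35-fold (6.89 ± 0.0401 in SW480 and 9.77 ± 0.0361 in SW620, n = 3 each).

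Of 18 measured genes downstream of Wnt signalling, 11 fell in SW620 and 5 rose, in all genes and adjusted over the list alone, and the median difference was -0.35. DKK4 led the fall, followed by APCDD1, a membrane inhibitor of Wnt (9.34-fold lower), and LEF1, a transcription factor of the pathway (4.37-fold lower), whereas LGR5 belongs to those that rose. As a set the Wnt targets did not pass camera (adjusted p = 0.166).

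Notch pathway genes were split. Of 25 measured, 5 rose and 11 fell over all genes, and 5 rose and 12 fell when adjusted over the list alone. MFNG was the most raised. The coactivator MAML2 rose 7.25-fold on the brighter of its features and differed by 0.0824 on the other, and the mean of its features differed by 1.47. The target gene HEY2 was 7.90-fold lower and the feedback inhibitor NRARP 7.05-fold lower. The set's adjusted p was 0.166 in camera.

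In the TGF-beta superfamily, members of the BMP branch changed in both directions. In SW620 BMP2 was 4.17-fold lower (-2.06, standard error 0.0988), BMP7 2.83-fold lower, and the BMP-responsive SMAD5 and SMAD9 were 3.42-fold and 2.88-fold lower. BMP4 and SMAD1, named here after their values were seen, rose 2.29-fold and 1.28-fold. Of 14 measured ligands, receptors and SMADs, 3 rose, 4 fell and 7 did not pass, and adjusted over the list alone the numbers were again 3 and 4. Of 12 measured TGF-beta and BMP targets, 2 rose and 6 fell by either adjustment. The inhibitory SMAD6 rose 7.03-fold, while the inhibitory SMAD7 was 2.03-fold lower. LTBP1, which holds latent TGF-beta in the matrix, was 1.55-fold lower. The brighter feature of TIMP3, an inhibitor of matrix proteases, fell by 0.76 on the log2 scale and its other feature differed by -0.0813, with a mean over both of -0.42. Both sets had an adjusted p of 0.454.

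Single epithelial and mesenchymal genes changed strongly, in both directions. Of 31 measured epithelial junction and polarity genes, 12 rose and 7 fell, the same numbers as adjusted over the list alone. The tight junction gene CLDN7 was 14.8-fold lower in SW620 (-3.89, standard error 0.10), the keratin KRT23 10.5-fold lower and the desmosomal cadherin DSC2 2.46-fold lower, while another claudin, CLDN1, rose 3.25-fold. The median of this list was 0.0747 and its mean -0.0491, so they differ in sign. Of 18 measured mesenchymal genes, 7 rose and 3 fell, or 8 and 3 adjusted over the list alone. THBS1, a matrix glycoprotein, rose 4.78-fold, the tropomyosin TPM2 rose 4.51-fold and the intermediate filament VIM rose 2.15-fold, and the other features of VIM differed by 1.24 and 0.93. FN1, the matrix protein fibronectin, was 3.67-fold lower. In camera the adjusted p was 0.454 for the epithelial and 0.190 for the mesenchymal list, so neither was shown to differ from other genes, while fry called the first down (adjusted p = 0.00486) and the second up (adjusted p = 0.00125).

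Of 28 measured G2/M and mitosis genes, 14 fell in SW620, 3 rose and 11 did not pass, with the same 14 and 3 adjusted over the list alone, and none changed by as much as 2-fold. The spindle checkpoint gene MAD2L1 fell by 0.91, the phosphatase CDC25C by 0.75, the checkpoint kinase BUB1 by 0.74 and cyclin A2, CCNA2, by 0.72 on the log2 scale. CCNB1, CDK1 and PLK1, named here after their values were seen, rose by 0.41, 0.45 and 0.32. Of 17 measured genes of cholesterol synthesis, 9 fell, 1 rose and 7 did not pass, with the same 9 and 1 adjusted over the list alone. STARD4, a cholesterol carrier, was 2.14-fold lower. INSIG1, which senses sterols, was 1.75-fold lower, and the enzymes NSDHL and HSD17B7 were 1.66-fold and 1.64-fold lower. Both lists missed the threshold in camera (adjusted p = 0.0714 for each, and 0.427 with an estimated correlation), with medians of -0.23 and -0.35. The G1/S and replication list was balanced, with 9 genes higher and 9 lower of 24 measured by either adjustment, and its median was 0.0214 and its mean -0.00924 (camera adjusted p = 0.936), with a median below 0 without SW480 replicate 3 (-0.0159) and also without SW620 replicate 1. Of these, the transcription factor E2F1 fell by 0.71, the helicase subunit MCM7 by 0.63 and the replication licensing factor CDC6 by 0.52 on the log2 scale, while the replisome subunit GINS3 rose by 0.60.

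Of 19 measured secretory and goblet cell markers of the intestine, 7 rose, 1 fell and 11 did not pass, with the same 7 and 1 adjusted over the list alone (camera adjusted p = 0.0943). FOXA2, a transcription factor of endoderm, rose 4.49-fold, and FOXA3 and the trefoil peptide TFF2 rose 1.85-fold and 1.86-fold. LYZ, the lysozyme of Paneth cells, rose 3.62-fold on its brighter feature and by 0.65 on the log2 scale on the other. Of 22 measured enterocyte markers, 3 rose, 4 fell and 15 did not pass, by either adjustment (adjusted p = 0.670). The adhesion molecules CEACAM5 and CEACAM6 rose 5.37-fold and 3.78-fold, whereas CDX2, the intestinal identity factor, was 2.90-fold lower and the lipid transfer protein MTTP 1.91-fold lower. Of 20 measured enteroendocrine and neural markers, 2 rose and 5 fell by either adjustment (adjusted p = 0.513). The neural adhesion molecule NCAM1 was 3.55-fold lower, PAX6 2.10-fold lower and UCHL1 1.46-fold lower. ISL1 fell by 0.48 (adjusted p = 0.0192), a call that rests on single arrays and on 1 of its features. Without SW480 replicate 1 its difference was -0.36 (adjusted p = 0.0862), without SW620 replicate 3 it was -0.32 (adjusted p = 0.0771), and the mean of its features differed by -0.20 (adjusted p = 0.164).

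Growth factor receptors included some of the largest single changes. EGFR was 10.3-fold lower in SW620 (-3.36, standard error 0.0905; 6.92 ± 0.0645 in SW480 and 3.55 ± 0.13 in SW620, n = 3 each). The ephrin receptor EPHB4 was 4.02-fold lower and the insulin receptor INSR 3.45-fold lower, whereas the orphan receptor ROR1 rose 3.98-fold. Of 33 measured receptor tyrosine kinases and EGF-family ligands, 6 rose and 10 fell, or 8 and 10 adjusted over the list alone. The list had a mean of -0.12 and pointed down in camera (adjusted p = 0.920), and its median of 0.0369 ran from -0.00864 without SW620 replicate 1 to 0.0886 without SW480 replicate 3. Of 27 measured immediate-early and stress genes, 4 rose and 13 fell by either adjustment (adjusted p = 0.145). JUN, a subunit of AP-1, rose 3.89-fold, while the asparagine synthetase ASNS was 2.84-fold lower and ATF3 1.92-fold lower. DUSP5, a phosphatase of ERK, was 2.25-fold lower on its brighter feature and differed by 0.0225 on the other, with a mean over both of -0.57.

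Of 19 measured hypoxia and glycolysis genes, 7 fell and 2 rose by either adjustment (adjusted p = 0.280). The 2 that rose were PGK1 (1.30-fold) and PGAM1 (1.25-fold), named here after their values were seen. ANKRD37 was 3.06-fold lower, NDRG1 2.79-fold lower and BNIP3L 1.58-fold lower. MXI1 fell by 0.75 on the log2 scale on its brighter feature and differed by 0.0404 on the other, with a mean over both of -0.36. Among matrix proteases and their inhibitors 2 rose and 8 fell of 25 measured by either adjustment (adjusted p = 0.424). The cathepsin CTSL was 3.47-fold lower and the sheddase ADAM17 2.33-fold lower, and TIMP1 rose 1.74-fold. Of 25 measured cytokines and chemokines, 5 rose and 2 fell by either adjustment (adjusted p = 0.525). CXCL16 was 8.02-fold lower, while CCL28, CXCL8 and CCL20 rose 2.27-fold, 2.13-fold and 1.92-fold. Of 25 measured interferon response genes, 4 rose and 3 fell by either adjustment (adjusted p = 0.670), among them IFIT5 (2.10-fold higher), USP18 (1.62-fold higher), BST2 (1.86-fold lower) and HERC5 (1.72-fold lower). CXCL8, BST2 and HERC5 were no brighter than the median feature. Of 7 measured antigen presentation genes, 2 fell and 0 rose by either adjustment (adjusted p = 0.513). They were the peptidases ERAP2 and ERAP1, 1.77-fold and 1.56-fold lower. None of the 8 measured members of the cancer-testis antigen list passed limma's test, over all genes or adjusted over the list alone (camera adjusted p = 0.719). The list held 41 genes, so this says nothing of such antigens that were not measured or not listed. CTAG2, with the smallest p of them, differed by 0.19 (adjusted p = 0.116).

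**Figure D3:**
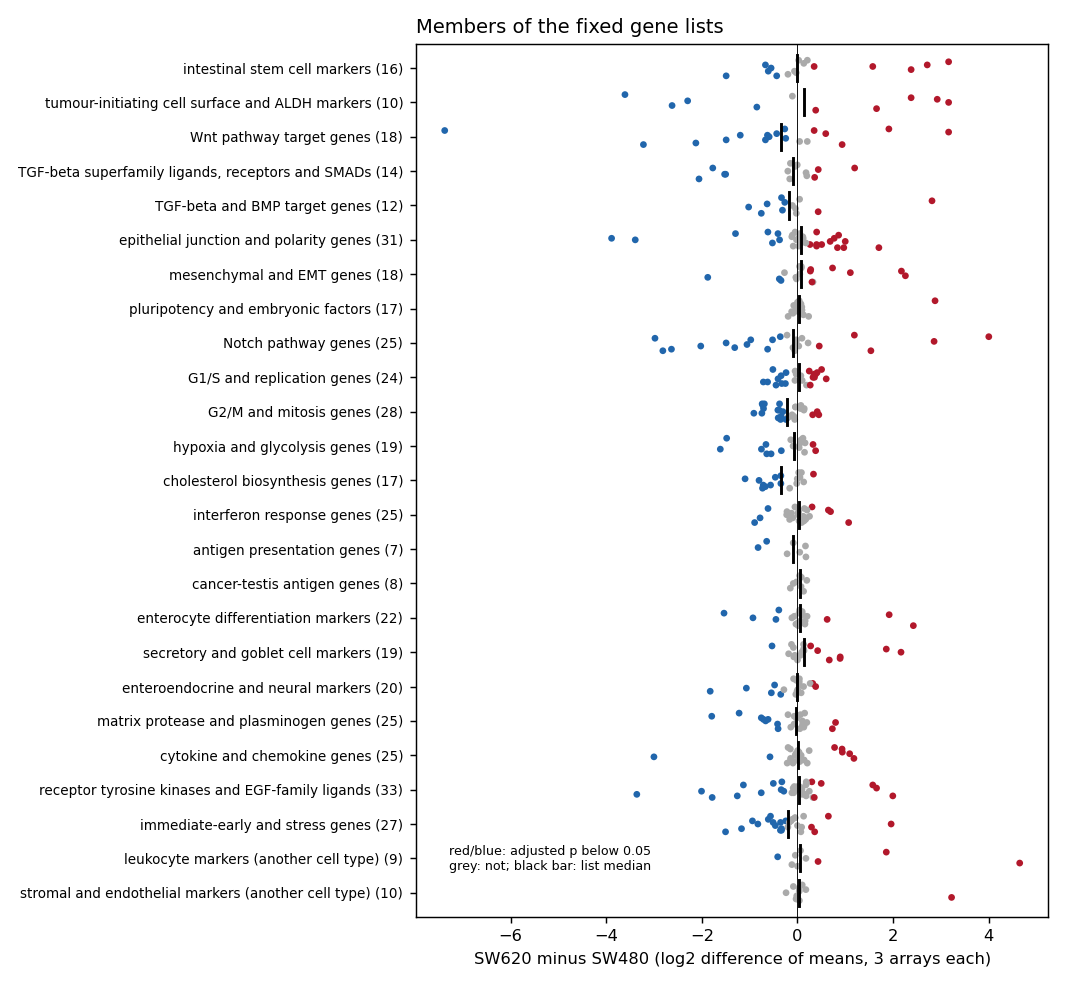
Log2 difference, SW620 minus SW480 spheroids, of each measured member (points) of the 25 gene lists, with a black bar at each list's median; red and blue points passed limma's test at an adjusted p below 0.05 and grey ones did not. Most lists hold members on both sides of 0, and the medians of the Wnt target, cholesterol synthesis and G2/M lists are -0.35, -0.35 and -0.23.

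Taking the 25 lists as sets, camera found 0 at an adjusted p below 0.05 and 6 at an unadjusted p below 0.05, and with an estimated correlation the numbers were 0 and 2. The rotation test fry, which asks whether a list's genes move on balance one way without comparing them with other genes, called 19 lists.

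Markers of cells that such cultures are not meant to hold were measured beside these groups. Of 9 leukocyte markers, 3 rose and 1 fell in SW620 by either adjustment (camera adjusted p = 0.190). They were LCP1 (25.1-fold higher), LYZ (3.62-fold higher on its brighter feature), CD68 (1.35-fold higher) and LAPTM5 (1.33-fold lower). The median of the 8 markers other than LCP1 was 0.0317. Of 10 stromal and endothelial markers 1 rose by either adjustment (camera adjusted p = 0.525), LUM, a proteoglycan of connective tissue. It rose 9.34-fold (4.73 ± 0.39 in SW480 and 7.95 ± 0.12 in SW620, n = 3 each), and the median of the other 9 was 0.0354.

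The genes of some chromosomes, taken as sets, lay higher or lower in SW620 than other genes, though not evenly along the chromosome. Chromosome 16 was shifted up as a set, with 187 of its 609 genes higher and 62 lower. Chromosomes 7 and 2 were shifted down, with 283 lower and 73 higher of 701 genes on chromosome 7, and 330 lower and 68 higher of 960 on chromosome 2. The median gene moved by 0.11 on chromosome 16, by -0.13 on chromosome 7 and by -0.0980 on chromosome 2. On chromosome 16, TOX3, PLLP and MTSS2 rose 9.91-fold, 7.38-fold and 6.91-fold. On chromosome 7, GLI3, a transcription factor of Hedgehog signalling, was 15.6-fold lower, EGFR 10.3-fold lower and the neuronal pentraxin NPTX2 9.55-fold lower. On chromosome 2 the largest falls were those of EPAS1, CXCR4 (12.2-fold) and LIMS3-LOC440895 (11.7-fold). The SW620 mean of LIMS3-LOC440895 (3.29) lay below the 25th percentile feature (3.53), as did that of EPAS1 (3.18).

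Of 23 chromosomes, 6 passed camera. The adjusted p was 7.07e-05 for chromosome 16, 8.34e-05 for 7, 0.000409 for 2, 0.0159 for 6, 0.0159 for 9 and 0.0446 for 10, with medians of 0.0816 for chromosome 6, -0.0864 for 9 and 0.0538 for 10. With an estimated correlation chromosomes 16 (adjusted p = 0.0474), 7 (adjusted p = 0.00554), 2 (adjusted p = 0.00690), 9 (adjusted p = 0.0474) and 10 (adjusted p = 0.0209) kept their call and 6 did not (adjusted p = 0.0609). Chromosome 10 lost its call without SW480 replicate 1 (adjusted p = 0.0605), without SW620 replicate 1 (adjusted p = 0.0508) and on ranks (adjusted p = 0.0628). Chromosome 11 passed camera on ranks only (adjusted p = 0.0312, against 0.0751 at the preset correlation). Among genes brighter than the median feature the medians were farther from 0, at 0.15 on chromosome 16, -0.34 on 7, -0.25 on 2, 0.15 on 6, -0.16 on 9 and 0.11 on 10.

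**Figure D4:**
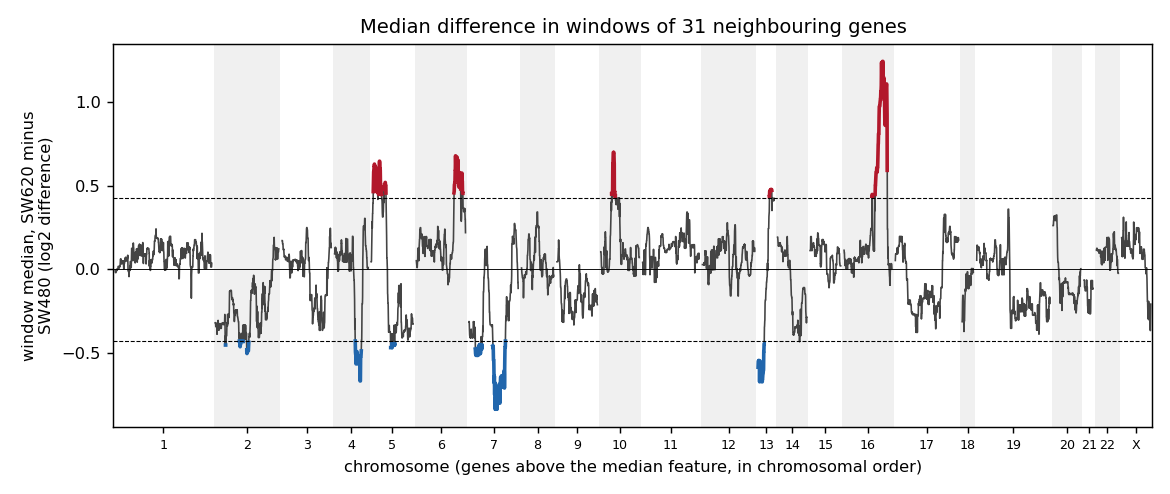
Median log2 difference, SW620 minus SW480 spheroids, in windows of 31 neighbouring genes (y axis) along each chromosome in gene order (x axis), for genes brighter than the median feature, a view chosen after the data had been seen. Windows beyond 0.43 on either side of the overall median form 14 stretches, and the highest single window, on chromosome 16, has a median of 1.25.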

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

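Of the counts given here, the one over protein-coding genes was chosen after the result was seen, and it gave 4705 changed genes, 824 of them at least 2-fold. Under the scalings, dim-feature filters, variance model and mean of features tried, the counts stayed within 1.5 times those reported, from 5059 to 5536 changed genes and from 869 to 909 at least 2-fold. The share of changed genes that was higher in SW620 ran from 42.1% with cyclic loess to 50% with 75th percentile centring, against 45.1% as deposited. Leaving out each array gave 4589 to 4984 changed genes, 893 to 910 at least 2-fold, and 5 to 6 chromosomes. An adjusted p below 0.01 gave 3930 genes. Testing all features separately gave 9450 changed and 1905 at least 2-fold. It adds features unnamed here, keeps every feature of a gene and adjusts over more tests, and these were not separated. The treat test with a minimum of 1.2-fold gave 2465, and a minimum of 1.5-fold or 3-fold gave 2143 or 350, as stricter or looser thresholds do. With the replicate block, 5218 genes changed, 5076 of them shared with the fit without it, and 904 were at least 2-fold; it changed no list's call. Same-numbered arrays deviated from their line's mean with r from -0.0107 to 0.0209, so the numbers do not pair the arrays. No alternative turned the direction of any of the 108 genes named by the rule, and 4 lost their call somewhere: ISL1 in 4 settings, and CDC6, CD68 and LAPTM5 under treat (adjusted p = 0.0521, 0.164 and 0.210).

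No list passed camera in any of the 17 other settings run for it, and treat was not run for lists. With fry, which does not compare a list with other genes, 21 chromosomes passed in place of 6, and 19 lists passed in place of 0. Its direction went against the median of the epithelial list (0.0747, adjusted p = 0.00486), of the stem cell list (-0.000858) and of the receptor kinase list (0.0369). The last 2 medians change sign when 1 array is left out, from -0.0407 (without SW620 replicate 2) to 0.0315 (without SW480 replicate 1) and from -0.00864 (without SW620 replicate 1) to 0.0886 (without SW480 replicate 3). For the others the medians were 0.14 (tumour-initiating markers), -0.35 (Wnt), -0.0978 (TGF-beta ligands, receptors and SMADs), 0.0789 (mesenchymal), 0.0382 (pluripotency), -0.0950 (Notch), -0.23 (G2/M), -0.0742 (hypoxia), -0.35 (cholesterol), -0.0889 (antigen presentation), 0.13 (secretory), -0.00304 (enteroendocrine), -0.0259 (protease), -0.20 (immediate-early), 0.0627 (leukocyte) and 0.0361 (stromal). Of these medians, the enteroendocrine one also changed sign when 1 array was left out, from -0.0233 to 0.0145. Scaling left the majority direction of changed members as it was in every list except the G1/S and enterocyte lists, where the numbers higher and lower were equal or nearly so. Signal over background was not measured here, which limits what can be said of genes near the floor. Among the genes named by the rule, LTBP1, BST2, HERC5, CEACAM6, MTTP, UCHL1, ISL1 and CXCL8 were no brighter than the median feature. Others, such as EGFR in SW620 (3.55) and PROM1 in SW480 (3.58), were below the median feature (4.065) in the dimmer line only. Their folds are uncertain too.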

Other observations

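The symbol families, the stretches of neighbouring genes and the splits of the arrays for the gene counts were tests chosen only after the result was seen. Families grouped by symbol root, and genes of them named here by size after their values were seen, showed changes mostly outside the lists above. The smallest p in camera belonged to the root DPY, where 7 of 10 genes, pseudogenes and non-coding transcripts were lower and 0 higher (6 lower with 75th percentile centring), followed by DDX, HERC and CST. Of 37 genes with the root DDX, mostly DEAD-box helicases, 15 rose and 3 fell, or 14 to 15 and 2 to 4 across the scalings. Of 11 genes and pseudogenes with the root HERC, 8 rose and 1 fell, and of 13 with the root STARD, 1 rose and 7 fell, under every scaling tried. Cross-hybridisation was not checked, so near-identical genes and pseudogenes of the DPY and HERC roots are uncertain, and their counts cannot be read as separate signals. Of 12 genes with the root CST, mostly cystatins that inhibit cysteine proteases, 5 were lower in SW620 and 0 higher under every scaling tried, led by CST5 (-3.76), CST1 (-1.98) and CST7 (-1.59). Of 10 HOXB genes and transcripts, 6 were lower and 0 higher under every scaling, among them HOXB2 (-0.88) and HOXB3 (-0.87). Of 17 synaptotagmin genes, which act in vesicle fusion, 4 rose by at least 2-fold, SYT11 (1.90), SYT17 (1.62), SYT1 (1.44) and SYT13, and 2 fell. Beside SOX2, the transcription factors SOX4 (1.91), which is also on the Wnt target list, and SOX5 (1.90) rose and SOX14 fell (-2.64). Of 54 keratin-root genes 8 rose and 6 fell, with KRT40 (3.01) and KRT80 (1.57) higher and KRT74 (-2.31) lower. As sets, 0 of 176 families passed camera after adjustment, 11 did at an unadjusted p below 0.05, and 2 did so with an estimated correlation. Outside the named features, 5182 of 37518 features unnamed here changed, and 972 of them differed at least 2-fold, 452 higher and 520 lower in SW620.

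Neighbouring genes moved together in long stretches. In windows of 31 genes brighter than the median feature, 1210 of 9471 genes (12.8%) lay inside 14 stretches on 9 chromosomes, 5 of them higher and 9 lower in SW620. The strongest were LINC02184 to COTL1 on chromosome 16 (170 genes, median 0.66, a 1.58-fold rise) and NCF1C to CADPS2 on chromosome 7 (146 genes, median -0.64, 1.56-fold lower). Others were MPHOSPH8 to EBPL on chromosome 13 (87 genes, -0.55), HSD17B11 to GATB on chromosome 4 (86 genes, -0.50), SESN1 to TULP4 on chromosome 6 (112 genes, 0.48) and UBE2QL1 to LINC01554 on chromosome 5 (147 genes, 0.46). With windows of 15 genes 340 genes lay inside such stretches, and with 61 genes 2702 did.

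A candidate explanation for these stretches is that the lines carry different numbers of copies of those chromosome regions. A chance order of genes is argued against, because 0 of 1000 random orders put as many genes inside stretches and the highest put 47. Neighbouring paralogs are argued against too: a new search with 1 gene kept per symbol root and chromosome put 1095 of 6978 genes inside stretches, 106% of the median after dropping as many genes at random. When stretches were found from every other gene, 630 of 771 left-out genes inside them (81.7%, 95% exact interval 78.8 to 84.4%) lay on the side of their stretch, with a median of 0.43 toward it, which fits a regional difference in dose. DNA was not measured, the genes in a stretch share 6 arrays, and broad co-regulation of neighbouring genes stays open.

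Of 4723 changed genes brighter than the median feature 928 (19.6%) lay inside the stretches, and of 869 with at least a 2-fold difference, 235 (27.0%) did. Since the stretches were found from the differences of these same genes, such counts give places and test nothing. The mitotic genes MAD2L1, BUB1 and CCNA2, the Wnt factor LEF1, SMAD5, SMAD9, CDX2, GLI3, EPAS1 and ASNS lay in stretches lower in SW620, and TOX3, PLLP, MTSS2, EFNB2 and RASGRF2 in stretches higher in it. PEG10, CADPS2 and LCP1 rose although their stretches were lower, and VAT1L and HEY2 fell although theirs were higher.

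The rise of LCP1, which leukocytes express strongly, could come from leukocytes in the SW620 cultures. The median of the 8 other measured leukocyte markers was 0.0317 (95% bootstrap interval -0.12 to 0.43), below 1.16, which is 25% of the LCP1 difference, and the markers ranged from -0.41 for LAPTM5 to 1.86 for LYZ. That argues against leukocytes as the source. LYZ is also on the secretory list. No other explanation of the rise in the tumour cells was tested.

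The rise of LUM could likewise come from stromal or endothelial cells. The median of the 9 other measured markers of these cells was 0.0354 (95% bootstrap interval -0.0867 to 0.0987), below 0.806, which is 25% of the LUM difference, and none of them lay above 0.18. That argues against such cells as the source, and why LUM rose in SW620 was not tested further.

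The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In every split other than the real one, each group holds arrays of both lines. The difference between the lines then adds to the spread within groups, so few or no gene calls were likely from them. The gene counts of those splits therefore do not exclude chance. For changed genes, 1 split, the real one, gave as many as 5294, and the highest of the others gave 0. For genes at least 2-fold apart, 1 split gave as many as 904 and the highest of the others gave 0. For chromosomes, 1 split gave as many as 6 and the highest of the others gave 3. For lists the real split gave 0 and so did the highest of the others, so all 10 splits gave as many.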
